A study of Mus musculus with 96 samples.

How the data were processed

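Polyadenylated RNA from the back-skin epidermis of female C57BL/6 mice kept in constant darkness was sequenced in 96 libraries, per the labels. They fall into 24 groups of 4 biological replicates, made of 4 genotypes at 6 circadian times (CT) spaced 4 h apart. The labels' protocols give separation of the epidermis with dispase, a stranded mRNA library kit and adaptors with unique molecular identifiers. Whether the identifiers were used to remove duplicates, and whether reads were counted by strand, is not given in the sources used here. Reads of near-identical paralogs, of overlapping genes and of antisense partners may therefore be divided in ways that cannot be traced.

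Per the submitters' processing notes, the tools were Trimmomatic 0.36, HISAT2 2.2.1, SAMtools 1.3.1, featureCounts 1.6.0 and edgeR, whose version is not given, with the mm10 mouse genome. Per the series design, the authors called rhythmic genes as a consensus of JTK_CYCLE and BIOCYCLE and sorted genes by shared rhythm parameters. The thresholds of that consensus are not given in the sources used here. The deposited data used here are 8 tables, 4 from each of these programs, each holding 22497 genes of 1 genotype. Per the file headers, the BIOCYCLE tables name every library by its CT and replicate number, and these names set the groups. The deposited values per library in these tables were log2 of library-scaled reads per kilobase (log2 RPKM) made by the authors. Each program's deposited p-value and q-value per gene were used for the consensus alone, and the deposited peak times in hours were read and not used. The JTK_CYCLE tables hold a further 96 columns of values per library whose codes match no label, and these columns were not used. The leading digit of the codes runs from 1 to 6 in the order of the columns in the WT and RERE tables, and is out of order in the EpiRE and BRE tables. What the digit stands for, and whether libraries of EpiRE and BRE were sorted or timed anew before deposit, is not given in the sources used here. All CT of these 2 genotypes rest on the column names of the BIOCYCLE tables.

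Whole reads were recovered from the log2 RPKM values for 22486 genes (99.95%), with 99.99% of their values within 0.1 read of a whole number. Gene lengths of the other 11 genes were solved from the library totals. The recovered prior was 0.25 reads and every library's scaling factor was 1, so all 4 genotypes share 1 scaling and levels were compared between tables. Recovered reads totalled 11.1 to 19.9 M per library, with a median of 15.2 M, and 15239 to 16101 genes had reads. They served for depth, for thinning and for limma-voom alone. Intervals and errors come from the spread between libraries, not from read counts.

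Rhythm was tested within each genotype with limma 3.58.1 in R 4.3.3 on the log2 values, with a cosine and a sine of 24 h and limma's moderated F test (empirical Bayes with a mean trend). Genes with a mean of at least 0 log2 RPKM (1 RPKM) over the libraries compared were tested. Differential rhythm was the moderated F test of genotype by cosine and sine in 5 contrasts of 48 libraries. Level was the genotype term beside CT as a factor of 6 times, by limma's moderated test. Benjamini-Hochberg adjusted p-values under 0.05 were called. These F tests have no side and all other tests were two-sided. Amplitude is the height of the fitted cosine above its mean on the log2 scale, so the trough-to-peak change is 2 times as large.

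The clock state of each library was measured by regressing its deviations from its genotype's mean, over 14 clock genes without Arntl, on the WT cosine coefficients, each WT library against a fit without itself. The length of the resulting vector is the magnitude (near 1 in WT by construction), and the length of the mean vector after turning each library back by its CT is the part locked to CT. Groups were compared by permutation tests with 100000 resamples within CT. The 2 arms of the clock were correlated after subtraction of CT means in each of the 4 genotypes. Amplitude ratios and phase differences were medians and circular means, with jackknife errors over libraries. They were taken over genes that passed an F test of 1 cosine fitted to both genotypes pooled. A gene rhythmic in only 1 of the genotypes can pass this test, and a fitted amplitude is above 0 for a flat gene too. Each gene was assigned to the best of 52 models of shared or absent rhythm by the Bayesian information criterion (BIC) where its weight was at least 0.5 and an F test of any rhythm over the 96 libraries passed.

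Fixed before the data were examined were 31 gene lists. They cover the clock (positive arm, negative arm with PAR bZIP factors, template, output), S phase, G2/M phase, basal keratinocytes, suprabasal differentiation, barrier lipids, cholesterol synthesis, glycolysis, oxidative phosphorylation, antioxidants, glucocorticoid response, heat shock, unfolded protein response, immediate early genes with dissociation, nucleotide excision repair, fasting response and interferon response. The others are markers of fibroblasts, muscle, myeloid and Langerhans cells, T cells, melanocytes, endothelium, adipocytes, hair follicle outer sheath and bulge, anagen hair shaft, sebaceous gland and red blood cells. In 23 lists, the clock template apart, at least 3 members were tested, and a score per library was put to permutation tests of rhythm (mean of the members' standardised values, CT shuffled, 92 tests) and of level (mean log2 value, genotype shuffled within CT, 115 tests), each family adjusted together. The named genes were fixed by rule as the clock lists with Cirbp and Rbm3; the 10 largest amplitudes, the 10 largest and 10 smallest fold changes and the 10 smallest p-values of differential rhythm per comparison, outside the clock lists for rhythm, with a mean of at least 5 RPKM in a group compared; the 4 members of each list with the smallest p; and 6 genes per model class of at least 20 genes. Coordinates come from the GENCODE vM21 annotation of GRCm38 (mm10).

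The fits were tested on simulated data drawn with the real means and residual SDs of the genes, with 200 genes changed per comparison, 100 at each of the sizes 0.2 and 0.4 log2. Noise was drawn independently for each gene, so the correlation between genes of real libraries was absent and false calls may be too few. Shuffled splits of the real RERE and WT libraries gave up to 333 level calls. Rhythms of these amplitudes were recovered in 49% and 89% of genes in WT, 54% and 91% in RERE, 50% and 88% in EpiRE and 62% and 85% in BRE, with 6, 11, 6 and 2 false calls. Differences of rhythm were recovered in 17% and 75% for EpiRE against WT, 27% and 81% for BRE against WT, 30% and 80% for RERE against WT, 19% and 77% for RERE against EpiRE and 35% and 78% for RERE against BRE, with 3, 11, 4, 7 and 7 false calls. Level differences in the same order were recovered in 56% and 93%, 63% and 90%, 63% and 89%, 59% and 88%, and 61% and 91%, with 8, 10, 6, 4 and 4 false calls. Of 3000 simulated genes, 38, 40, 41 and 47 of 50 with a rhythm of 0.4 in WT, WT and RERE, those with EpiRE, and all genotypes were placed in their class, and 5 of 2800 unchanged genes were placed in any.

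Alternatives were an adjusted p of 0.01, added pseudocounts of 0.1 and 1, a mean of at least 5 RPKM, no filter, no trend, median-of-ratios scaling, quantile normalisation, CT as a factor, no CT term, the spread shared over all 96 libraries, a replicate block, each replicate number or library left out in turn, a template from RERE, the template genes alone for amplitude and phase, a BIC weight of 0.8 and other thresholds of the consensus. Added after the data were seen were limma-voom on recovered reads and leaving out the EpiRE and BRE libraries whose clock state stood apart. Each model count was set against 100 splits of its libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table (version 1.17.8), did the rest.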

Results

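The series measured messenger RNA by sequencing in back-skin epidermis of mice whose circadian clock ran in all tissues, in brain and epidermis together, in epidermis, or in brain. Arntl encodes BMAL1, an activator that the molecular clock needs. Per the labels, WT mice carried intact Arntl with both Cre drivers. The other genotypes carried an Arntl allele stopped by a floxed cassette, which Cre removes. RERE mice had both K14Cre, active in epidermis, and Syt10-Cre, active in the brain clock. EpiRE mice had K14Cre and BRE mice had Syt10-Cre. Each genotype was sampled at 6 circadian times in constant darkness with 4 libraries per time, which makes 24 libraries per genotype. The labels name 4 mice per time as biological replicates, 8-week-old females, so p-values are over animals. Recovered totals were 11.1 to 19.9 M reads per library, with means of 15.4 M in WT, 14.8 M in RERE, 14.8 M in EpiRE and 15.0 M in BRE. Levels are given as mean log2 RPKM with the SD over 24 libraries of a genotype or 4 libraries of a time, and amplitudes, peak times and differences with their SE. Adjusted p-values of genes are from limma.

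The targeted gene came first. Arntl (ENSMUSG00000055116; chromosome 7, 113207465 to 113314126, mm10) had a mean of 3.88 (SD 0.83, n = 24) in WT, 3.89 (SD 0.78, n = 24) in RERE, 4.16 (SD 0.31, n = 24) in EpiRE and 3.88 (SD 0.14, n = 24) in BRE. BRE lay 0.01 above WT (permutation p = 0.968), -0.01 from RERE (permutation p = 0.940) and -0.28 from EpiRE (permutation p = 6e-05). EpiRE lay 0.28 above WT (permutation p = 0.0293), a difference that did not pass without replicate 4 (permutation p = 0.0715). The level of the whole gene therefore did not set BRE apart from WT. The place of the stop in the gene is not given in the sources used here, and a count over the whole gene does not tell stopped from complete transcripts, so the level does not check the genotype. Its time course did differ. Arntl oscillated with an amplitude of 1.1 ± 0.07 peaking at CT 22.0 in WT (adjusted p = 5.4e-10) and 1.01 ± 0.08 peaking at CT 22.5 in RERE (adjusted p = 1.5e-08). The amplitude was 0.21 ± 0.08 in EpiRE (adjusted p = 0.364) and 0.06 ± 0.04 in BRE (adjusted p = 0.618). The interaction test of rhythm against WT gave an adjusted p of 7.1e-06 for EpiRE and 6.36e-12 for BRE.

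**Figure D1:**
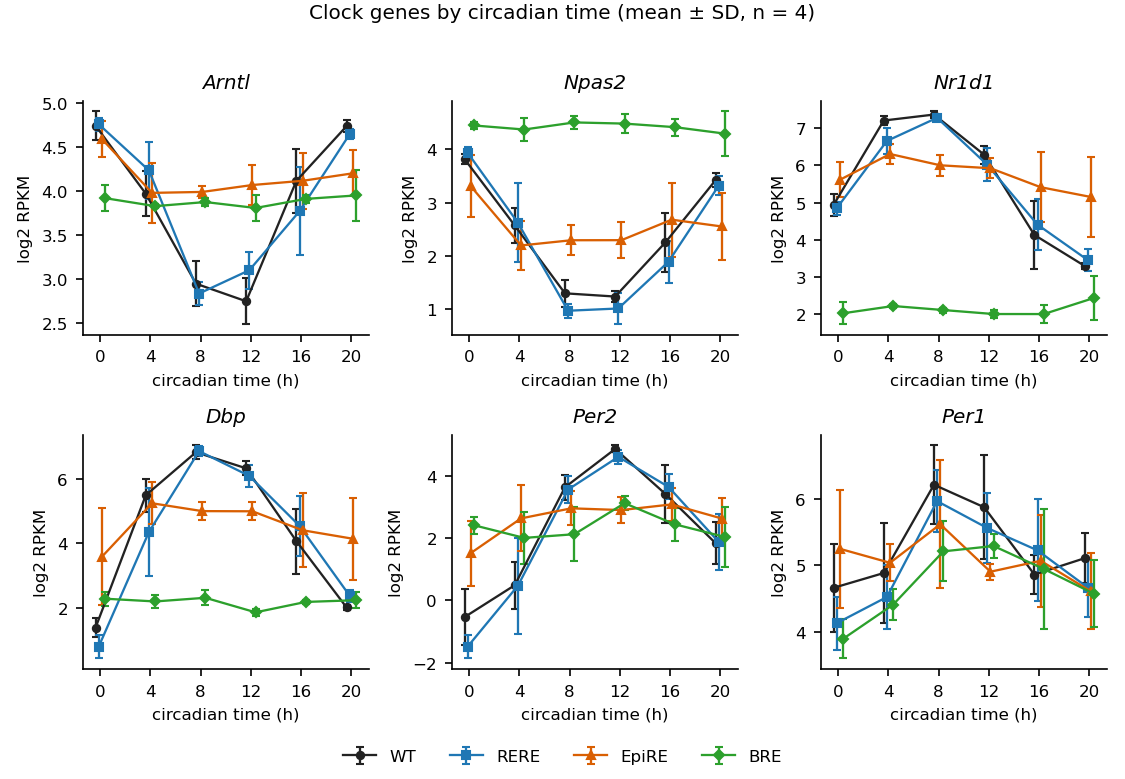
Mean log2 RPKM (± SD, n = 4 libraries) of Arntl, Npas2, Nr1d1, Dbp, Per2 and Per1 against circadian time in hours for WT, RERE, EpiRE and BRE. WT and RERE oscillate together, EpiRE has amplitudes of 0.51 for Nr1d1 and 0.68 for Dbp that were not called, and in BRE only Per1 was called (amplitude 0.66).

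The first question was which epidermal genes follow a day in mice with a clock in all tissues. In WT the clock itself oscillated strongly. Npas2 (ENSMUSG00000026077; chromosome 1, 39193731 to 39363236), a partner of BMAL1, fell from 3.81 (SD 0.09, n = 4) at CT0 to 1.24 (SD 0.11, n = 4) at CT12. Nr1d1 (ENSMUSG00000020889; chromosome 11, 98767932 to 98775333), the repressor REV-ERB alpha, stood at 7.37 (SD 0.09, n = 4) at CT8 and 3.30 (SD 0.09, n = 4) at CT20. Dbp (ENSMUSG00000059824; chromosome 7, 45705088 to 45710203), a PAR bZIP output factor, had the amplitude 2.85 ± 0.18 with its peak at CT 9.39 (adjusted p = 1.3e-10). Per2 (ENSMUSG00000055866; chromosome 1, 91415982 to 91459324), a repressor of the loop, reached 2.61 ± 0.20 at CT 12.5. All 6 tested genes of the positive arm and all 11 of the negative arm with PAR bZIP factors were called (6 and 11 adjusted over the list alone), and both list means were rhythmic (adjusted p = 0.000184 each). The cold-inducible RNA-binding genes Cirbp (0.34 ± 0.08, peak CT 5.31) and Rbm3 (0.32 ± 0.05, peak CT 8.02) were rhythmic as well. Of 11087 genes tested, 3675 were rhythmic in WT, with a median amplitude of 0.193, of which 236 reached 0.5 and 27 reached 1. Their peaks were most frequent from CT12 to CT16 (916 genes, 24.9%). The count was 2322, 2055 and 2019 without replicates 1, 2 and 4, and 2249 with CT as a factor.

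Among genes outside the clock with a mean of at least 5 RPKM in WT, several of the largest amplitudes were of cell cycle genes. The mitotic ubiquitin-conjugating enzyme Ube2c (ENSMUSG00000001403; chromosome 2, 164769898 to 164778822) oscillated by 1.02 ± 0.10 with a peak at CT 23.6 (adjusted p = 6.92e-07). Ccnb2 (ENSMUSG00000032218; chromosome 9, 70407692 to 70421547), a mitotic cyclin, followed with 0.96 ± 0.10. All 20 genes of the G2/M list were called (20 adjusted over the list alone), and the list mean peaked at CT 22.8 (adjusted p = 0.000184). Of 19 S phase genes 18 were called (18 adjusted over the list alone), with the list mean highest at CT 13.5 (adjusted p = 0.00697). The replicative helicase gene Mcm6 (ENSMUSG00000026355; chromosome 1, 128331590 to 128359664) stood at 4.68 (SD 0.12, n = 4) at CT12 and at 3.88 (SD 0.34, n = 4) at CT4. Stfa3 (0.99 ± 0.22), a member of a family of near-identical stefins whose reads may be shared, the serpin Serpinb12 (0.98 ± 0.09) and the transglutaminase Tgm3 (0.89 ± 0.18) were further genes of large amplitude.

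Of the other fixed lists, 2 were rhythmic as lists in WT. The list of basal keratinocyte genes peaked at CT 6.57 (adjusted p = 0.0289), with 4 of 11 members called (6 adjusted over the list alone), among them Dst (0.51 ± 0.07), a hemidesmosome linker, and Col17a1 (0.19 ± 0.03). Oxidative phosphorylation peaked at CT 0.73 (adjusted p = 0.0335), with 11 of 19 members called (14 adjusted over the list alone), among them the ATP synthase subunit Atp5b (0.14 ± 0.03). Of 6 lists called in WT with the clock and cell cycle lists, 4, 4, 3 and 5 were called without replicates 1, 2, 3 and 4. The remaining lists did not pass as lists. Called over all genes, and adjusted over the list alone in parentheses, were 5 (5) of 7 clock output genes, 4 (4) of 16 suprabasal differentiation genes, 4 (6) of 13 barrier lipid genes, 8 (11) of 20 cholesterol synthesis genes and 6 (7) of 13 glycolysis genes. The same counts were 6 (9) of 14 antioxidant genes, 7 (7) of 12 glucocorticoid response genes, 9 (10) of 14 heat shock genes, 7 (8) of 12 unfolded protein response genes, 2 (0) of 12 immediate early and dissociation genes, 4 (4) of 11 nucleotide excision repair genes, 8 (8) of 9 fasting responsive genes and 3 (3) of 7 interferon response genes. Examples are the cell cycle kinase Wee1 (0.58 ± 0.13), the ceramide pathway lipoxygenase Aloxe3 (0.55 ± 0.07), the mitochondrial superoxide dismutase Sod2 (0.37 ± 0.03), the chaperones Calr (0.45 ± 0.06) and Hsph1 (0.49 ± 0.10), and the damage sensor Xpc (0.23 ± 0.04). Among markers of other cells, the T cell and stromal marker Thy1 (0.81 ± 0.10) was the 1 member called of 6 T cell markers (1 adjusted over the list alone). The hair follicle list had 1 of 6 members called (0 adjusted over the list alone), myeloid and Langerhans markers 0 of 6 (0) and sebaceous gland markers 0 of 5 (0). Too few genes were tested for a list test of fibroblast (1 of 1 called), muscle (0 of 1), melanocyte (0 of 1) and anagen hair shaft markers (0 of 2), while endothelial and adipocyte lists had 0 tested genes and red blood cell markers had 1, called in 0 genotypes.

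RERE mice ask whether clocks in brain and epidermis are enough for the epidermal rhythm. In RERE the clock genes oscillated at sizes near those of WT, with Npas2 at 1.55 ± 0.10, Nr1d1 at 1.87 ± 0.10, Dbp at 2.82 ± 0.23 and Per2 at 2.87 ± 0.24. All 6 positive-arm genes and 10 of 11 negative-arm genes were called (6 and 11 adjusted over the list alone), and both list means were rhythmic (adjusted p = 0.000184 each). Ccnb2 (1.06 ± 0.16, peak CT 23.6), Ube2c (1.01 ± 0.15), the glutamine synthetase gene Glul (0.98 ± 0.14, peak CT 12.8) and the chemokine gene Cxcl14 (0.87 ± 0.07, peak CT 23.8) had large amplitudes among genes with a mean of at least 5 RPKM, as did Cenpa and Cdc20. G2/M genes were called in 20 of 20 (20 adjusted over the list alone; list peak CT 22.9, adjusted p = 0.00759) and S phase genes in 16 of 18 (17; list peak CT 12.7, adjusted p = 0.00184). Clock output (3 of 7 called, 5 adjusted over the list alone; adjusted p = 0.0136) and interferon response (2 of 6, 4 adjusted over the list alone; adjusted p = 0.0289), with Bst2 at 0.53 ± 0.11 and Ifi27l2a at 0.48 ± 0.08, were also rhythmic as lists. Of 6 lists called in RERE, 5, 4, 3 and 4 were called without replicates 1, 2, 3 and 4.

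In RERE 2136 of 11032 genes were called, with a median amplitude of 0.211, and 1496 genes were called in both RERE and WT where 710 would be shared by independent lists. The libraries of these 2 genotypes are separate. The RERE count was 894, 875 and 1157 without replicates 2, 3 and 4. Fitted peaks of the shared genes lay 0.973 h apart in the median, and 97.2% lay within 4 h. RERE peaks were most frequent from CT12 to CT16 (832 genes, 39.0%) and rare from CT4 to CT8 (69 genes, 3.23%). The count of called genes was lower in RERE than in WT, yet the interaction test by limma found 0 of 11051 genes whose rhythm differed between them. At an unadjusted p under 0.05 there were 837, and limma-voom found 0. The smallest p belonged to the kinase gene Sgk1 (amplitude 0.37 in RERE and 0.26 in WT, adjusted p = 0.358). Without the RERE library of CT16 replicate 4 the count was 1. The F test of 1 cosine fitted to RERE and WT pooled was passed by 5615 genes. Over these the median amplitude ratio of RERE to WT was 0.886 ± 0.148 (jackknife SE), and 62.4% of genes were smaller in RERE. For the 14 clock template genes the ratio was 1.00 ± 0.11. The phase differed by -0.46 ± 0.44 h over the 5615 genes and by 0.50 ± 0.38 h over the template genes, so its direction was not settled.

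Levels differed between RERE and WT in 236 of 11051 genes, 87 higher and 149 lower. Krt1 (ENSMUSG00000046834; chromosome 15, 101845426 to 101850794), the keratin of differentiating layers, was higher by 0.42 ± 0.05 and Tgm3 (ENSMUSG00000027401; chromosome 2, 130012349 to 130050399) by 0.88 ± 0.21. The serpins Serpinb3b (0.80 ± 0.13) and Serpinb12 (0.75 ± 0.14) and the stefin genes BC100530 (1.18 ± 0.30) and Stfa3 (0.93 ± 0.20), whose families hold near-identical copies, were higher too. Among the genes that were lower were Ndufa4l2 (ENSMUSG00000040280; chromosome 10, 127514967 to 127517154) at -0.84 ± 0.12, the vascular growth factor gene Vegfa (ENSMUSG00000023951; chromosome 17, 46016993 to 46032369) at -0.70 ± 0.10 (adjusted p = 4.5e-06) and the prolyl hydroxylase gene Egln3 at -0.51 ± 0.13. Of 13 glycolysis genes 7 fell (12 adjusted over the list alone), among them Tpi1 at -0.24 ± 0.05 and Pgk1 at -0.21 ± 0.05, and the list mean fell by 0.16 (adjusted p = 0.000805). The barrier lipid list rose by 0.13 (adjusted p = 0.0343), with 4 of 13 members higher (5 adjusted over the list alone), among them Aloxe3 at 0.35 ± 0.08. The interferon list fell by 0.25 (adjusted p = 0.00743; 0 of 7 members called, 3 adjusted over the list alone) and the hair follicle list by 0.38 (adjusted p = 0.01; 0 of 6, 3 adjusted over the list alone). The suprabasal list lay 0.24 higher without passing (adjusted p = 0.0528; 2 of 16 members higher, 4 adjusted over the list alone). The 4 lists called became 1, 7, 3 and 3 without replicates 1, 2, 3 and 4. The count of 236 genes was 60 without replicate 1, 108 without replicate 3 and 48 without replicate 4.

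EpiRE mice ask what an epidermal clock does on its own. In EpiRE no gene of the 2 clock arms was called. Npas2 had an amplitude of 0.37 ± 0.15 (adjusted p = 0.428), Nr1d1 0.51 ± 0.16 (adjusted p = 0.334) and Dbp 0.68 ± 0.26 (adjusted p = 0.386). None of 6 positive-arm and 11 negative-arm genes was called (1 and 0 adjusted over the list alone). The G2/M list (0 of 20 called, 13 adjusted over the list alone; list adjusted p = 0.127), the S phase list (0 of 19, 0 adjusted over the list alone; adjusted p = 0.5) and all other tested lists did not pass either. With limma 0 of 11061 genes were rhythmic in EpiRE, with 1397 at an unadjusted p under 0.05 and 0 by limma-voom. The count was 2 without the EpiRE library of CT4 replicate 3. Treating CT as a factor instead of a 24 h cosine called 199 genes that differed between times in EpiRE, and sharing the spread over all 96 libraries called 94 rhythmic genes. The CT of EpiRE and BRE libraries rests on the column names of 1 kind of table, while the library codes of the other kind are out of order in these 2 genotypes, and libraries at a wrong CT would also lower the count.

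Clock states of single libraries were measured against the WT time course. Their mean magnitude was 1.02 (SD 0.15, n = 24) in WT, 1.01 (SD 0.21, n = 24) in RERE, 0.373 (SD 0.26, n = 24) in EpiRE and 0.166 (SD 0.13, n = 24) in BRE. EpiRE lay 0.206 above BRE (permutation p = 0.00045), and still by 0.15 (permutation p = 2e-04) without the 3 EpiRE and BRE libraries that stood apart from their groups. EpiRE lay -0.65 from WT, and RERE lay 0.633 above EpiRE and 0.839 above BRE (permutation p = 1e-05 each, the smallest that the permutations can give). RERE and WT differed by -0.017 (permutation p = 0.665). The part of the state that followed CT was 0.991 ± 0.033 in WT, 0.968 ± 0.042 in RERE, 0.243 ± 0.063 in EpiRE and 0.048 ± 0.023 in BRE. Some EpiRE libraries held a state as large as WT, with 1.12 at CT0 replicate 3 and 0.972 at CT20 replicate 1, both near the phase of their own CT (23.2 and 19.1). Others stood at a phase away from their CT, such as CT4 replicate 3 (0.447 at CT 11.6) and CT16 replicate 3 (0.379 at CT 10.6). Within each time the positive and negative arms of the clock correlated across EpiRE libraries with r = -0.518 (permutation p = 0.0487, adjusted p = 0.195 over the 4 genotypes) and rho = -0.433 (permutation p = 0.0858, adjusted p = 0.343), which did not pass. Without the 2 farthest libraries r was -0.530. The same r was -0.054 in WT (permutation p = 0.840), -0.182 in RERE (permutation p = 0.420) and 0.270 in BRE (permutation p = 0.216), with rho of -0.139, -0.208 and 0.203. Under median-of-ratios scaling r was 0.607 in BRE (permutation p = 0.00772) and 0.0952 in WT.

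**Figure D2:**
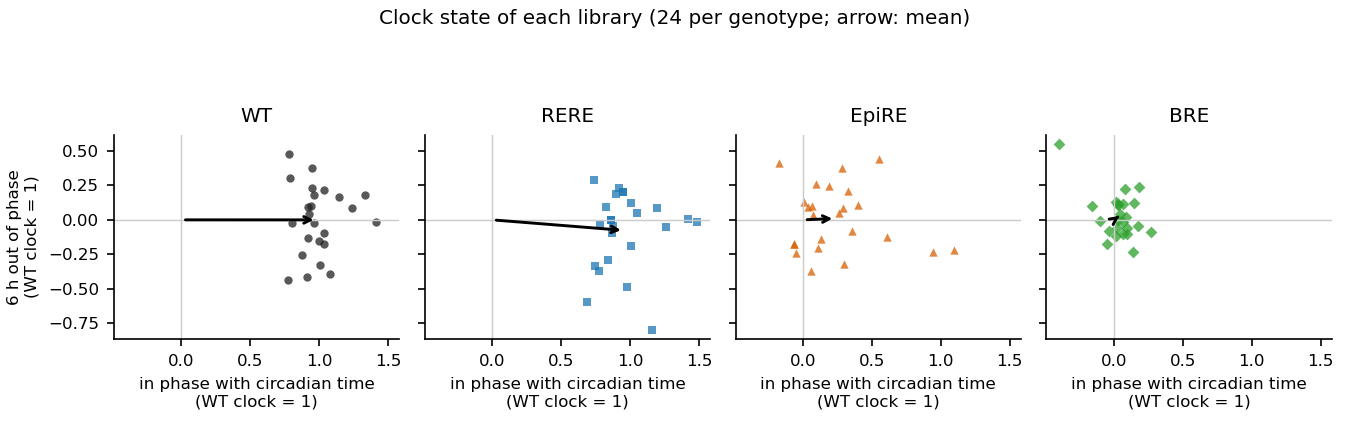
Clock state of each library, 24 points per genotype, with the part in phase with circadian time on the x axis and the part 6 h out of phase on the y axis, both relative to the WT clock (1), and an arrow for the mean. The mean arrow has a length of 0.991 in WT, 0.968 in RERE, 0.243 in EpiRE and 0.048 in BRE.

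Rhythms differed between EpiRE and WT in 174 of 11059 genes by the interaction test. The list holds 4 of 6 positive-arm genes (5 adjusted over the list alone) and 9 of 11 negative-arm genes (9). Outside the clock, amplitudes in EpiRE and WT were 0.08 and 0.52 for the tenascin gene Tnxb (adjusted p = 0.000102), 0.15 and 0.98 for Serpinb12, 0.03 and 0.39 for the retinol dehydrogenase gene Rdh12, 0.14 and 0.62 for the cyclin gene Ccnd1, 0.08 and 0.37 for Sod2 (ENSMUSG00000006818; chromosome 17, 13006846 to 13040063) and 0.09 and 0.71 for the pyridoxal kinase gene Pdxk (ENSMUSG00000032788; chromosome 10, 78436744 to 78464975). S phase genes were called in 5 of 19 (19 adjusted over the list alone) and G2/M genes in 0 of 20 (15). The F test of 1 cosine fitted to EpiRE and WT pooled was passed by 3273 genes, which need not be rhythmic in EpiRE. Over these the amplitude in EpiRE was 0.580 ± 0.126 of that in WT, against 0.235 ± 0.069 for the clock template genes. Fitted amplitudes are above 0 for flat genes too, so the ratio does not give the rhythm kept in EpiRE. The count of 174 was 278 without the EpiRE library of CT0 replicate 3, 293 without that of CT8 replicate 1, 110 without the WT library of CT4 replicate 4 and 294 without the EpiRE libraries that stood apart. It was 37 without replicate 2 and 39 without replicate 4.

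Levels differed between EpiRE and WT in 247 of 11059 genes, 103 higher and 144 lower. Krt1 (0.42 ± 0.07) and Tgm3 (1.09 ± 0.18) were the 2 of 16 suprabasal genes that rose (2 adjusted over the list alone; list difference 0.09, adjusted p = 0.615). The stefin genes BC100530 (1.22 ± 0.32), Stfa1 (1.17 ± 0.30) and Stfa3 (0.93 ± 0.23) and the serpin gene Serpinb3b (0.81 ± 0.13) also rose. Ndufa4l2 (-0.77 ± 0.10, adjusted p = 7.4e-06), Vegfa (-0.73 ± 0.12) and the arginase gene Arg1 (-0.78 ± 0.19) fell. Glycolysis fell by 0.15 as a list (adjusted p = 0.01), with 6 of 13 members lower (10 adjusted over the list alone), among them Tpi1 at -0.28 ± 0.05 and Eno1 at -0.23 ± 0.05. The hair follicle outer sheath and bulge list fell by 0.44 (adjusted p = 0.000719), with 3 of 6 members lower (6 adjusted over the list alone), namely Lhx2 (ENSMUSG00000000247; chromosome 2, 38339281 to 38369733), a hair follicle stem cell factor, at -0.82 ± 0.14, Krt17 at -0.30 ± 0.08 and Krt79 at -0.35 ± 0.10. Both this contrast and that of RERE use the same WT libraries. The count of 247 genes was 97 without replicate 2, 147 without replicate 3 and 55 without replicate 4.

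BRE mice hold the brain clock without an epidermal clock, and the question was which epidermal rhythms remain. Some glucocorticoid-responsive genes were rhythmic, though their list did not pass. Tsc22d3 (ENSMUSG00000031431; chromosome X, 140539528 to 140600659), also called GILZ, rose from 4.09 (SD 0.21, n = 4) at CT0 to 5.51 (SD 0.47, n = 4) at CT12 in BRE, as it rose from 3.98 (SD 0.24, n = 4) to 5.35 (SD 0.84, n = 4) in WT. Its amplitude in BRE was 0.74 ± 0.13 with a peak at CT 12.5 (adjusted p = 0.0198). Fkbp5 (ENSMUSG00000024222; chromosome 17, 28399094 to 28517527), a chaperone of the glucocorticoid receptor, had 1.01 ± 0.22 at CT 12.5 (adjusted p = 0.0433) and Zbtb16 (ENSMUSG00000066687; chromosome 9, 48654297 to 48836222) 0.77 ± 0.16 at CT 11.8 (adjusted p = 0.0392). Of 12 members 3 were called in BRE (5 adjusted over the list alone), 7 in WT (7), 2 in RERE (5) and 0 in EpiRE (0). The median amplitude of the members was 0.228 in EpiRE and 0.163 in BRE, and that of Fkbp5 alone was 0.15 in EpiRE. The list mean did not pass (adjusted p = 0.0607 in BRE and 0.230 in WT), and no member's rhythm was called different between genotypes in any of the 5 contrasts over all genes. Of the 2 arms of the clock, Per1 (ENSMUSG00000020893; chromosome 11, 69095217 to 69109960) alone was called in BRE over all genes, at 0.66 ± 0.13 with a peak at CT 11.8 (adjusted p = 0.0281), and its rhythm was not called different from WT (0.67 ± 0.17; adjusted p = 0.664). Positive-arm genes were called in 0 of 6 (0 adjusted over the list alone) and negative-arm genes in 1 of 10 (1). Rbm3 (0.38 ± 0.07, peak CT 6.33), Glul (0.75 ± 0.13, peak CT 11.5) and Dst (0.29 ± 0.05, peak CT 12.6) were also called.

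**Figure D3:**
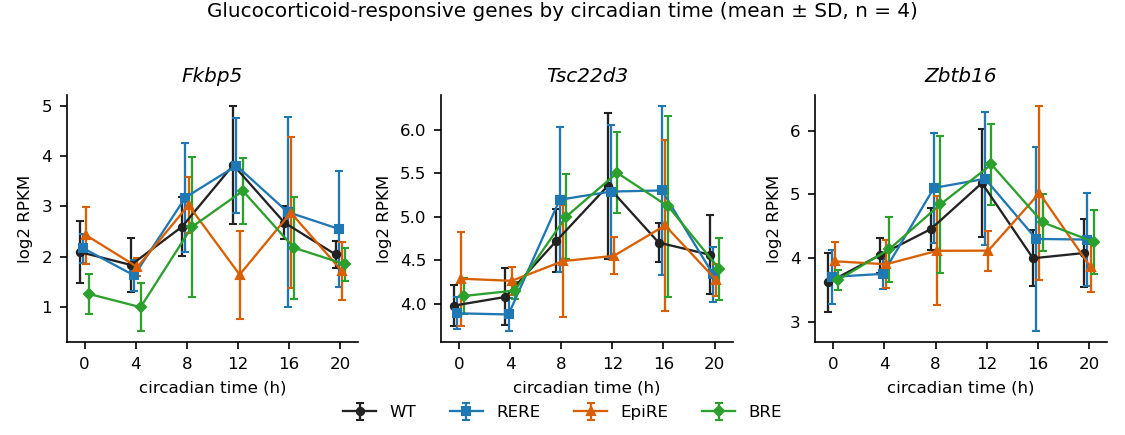
Mean log2 RPKM (± SD, n = 4 libraries) of Fkbp5, Tsc22d3 and Zbtb16 against circadian time in hours in WT, RERE, EpiRE and BRE. BRE peaks at CT 12.5 for Fkbp5 and Tsc22d3 and CT 11.8 for Zbtb16.

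The 3 S phase genes called in BRE had their peaks at another time than in WT. Mcm6 stood at 4.41 (SD 0.04, n = 4) at CT0 and 3.58 (SD 0.12, n = 4) at CT12 in BRE, with a peak at CT 0.79 (adjusted p = 0.0392) where WT peaked at CT 12.4. Gins2 (ENSMUSG00000031821; chromosome 8, 120578633 to 120589304), a part of the replicative helicase, peaked at CT 1.34 in BRE and CT 10.8 in WT, and Mcm2 at CT 0.24 and CT 12.4. Of 18 S phase genes 3 were called in BRE (13 adjusted over the list alone), with a list peak at CT 0.15 that did not pass (adjusted p = 0.0543). The rhythm differed from WT in 15 of 19 S phase genes (19 adjusted over the list alone). E2f1 (ENSMUSG00000027490; chromosome 2, 154559407 to 154569892), a transcription factor of S phase entry, had amplitudes of 0.41 in BRE with a peak at CT 0.12 and 0.79 in WT with a peak at CT 12.4 (adjusted p = 1.56e-07 for the difference). None of 20 G2/M genes was called in BRE (0 adjusted over the list alone; list adjusted p = 0.483), and 9 differed from WT (15 adjusted over the list alone). In all 627 of 11016 genes differed in rhythm between BRE and WT, among them 5 of 6 positive-arm genes (6 adjusted over the list alone), 9 of 11 negative-arm genes (10), Ttc9 (ENSMUSG00000042734; chromosome 12, 81631249 to 81667557; amplitude 0.07 in BRE and 1.05 in WT, adjusted p = 1.53e-10), the cyclin gene Ccnd2 (0.08 and 0.81) and Sod2 (0.10 and 0.37). The count was 380, 359, 315 and 305 without replicates 1, 2, 3 and 4.

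**Figure D4:**
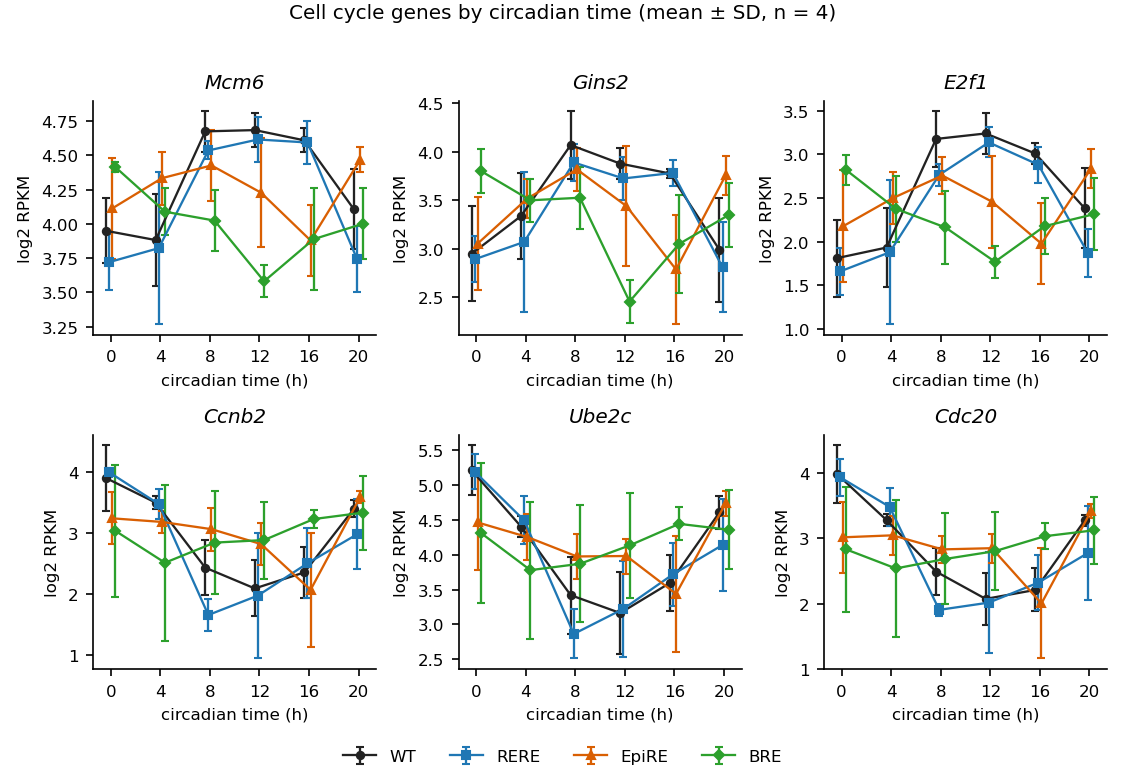
Mean log2 RPKM (± SD, n = 4 libraries) of Mcm6, Gins2, E2f1, Ccnb2, Ube2c and Cdc20 against circadian time in hours in WT, RERE, EpiRE and BRE. Mcm6 stands at 4.68 in WT and 3.58 in BRE at CT12, and the mitotic genes Ccnb2 and Ube2c oscillate by 0.96 and 1.02 in WT.

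Altogether 125 of 10970 genes were called rhythmic in BRE, with a median amplitude of 0.261 and peaks mainly from CT0 to CT4 (42 genes, 33.6%) and CT12 to CT16 (37 genes, 29.6%). The count was 31 with CT as a factor, 54 without a filter, 2 at an adjusted p under 0.01 and 183 under median-of-ratios scaling. The unfolded protein response passed as a list (adjusted p = 0.0418, peak CT 18.9), with 1 of 12 members called (6 adjusted over the list alone), Herpud1 at 0.24 ± 0.05. It did not pass under median-of-ratios scaling, where 0 lists did. Heat shock (1 of 14, 7 adjusted over the list alone; list adjusted p = 0.0544), with Hsp90aa1 at 0.27 ± 0.05, and the other lists did not pass. Of 124 BRE genes tested in WT too, 75 were called in both, where 41.3 would be shared by independent lists, and 77.3% of them peaked within 4 h. With RERE 62 were shared, where 24.1 would be. The count of 125 moved down or up with single libraries. Leaving out 1 library at a time, it was 73, 37 and 39 without CT0 replicates 2, 3 and 4, 79, 241 and 54 without CT4 replicates 1, 3 and 4, 59 and 232 without CT8 replicates 2 and 4, 49, 54, 41 and 43 without CT12 replicates 1, 2, 3 and 4, 348 and 32 without CT16 replicates 3 and 4, and 83 and 312 without CT20 replicates 2 and 3. It was 41, 0, 198 and 9 without replicates 1, 2, 3 and 4 at every time.

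Levels of BRE differed from WT more widely than those of any other genotype, in 4066 of 11016 genes, 220 of them by over 1.5-fold. The higher and lower genes numbered 1382 and 2684, against 1903 and 1807 under median-of-ratios scaling and 1916 and 1776 after quantile normalisation, so the balance of directions depended on the scaling. The median of all genes was -0.05 as deposited and -0.01 under median-of-ratios scaling. Of 6 positive-arm genes 5 rose (5 adjusted over the list alone; list difference 0.98, adjusted p = 0.000164), with Npas2 at 1.98 ± 0.17 and Cry1 (ENSMUSG00000020038; chromosome 10, 85131700 to 85185064) at 1.67 ± 0.15. Of 11 negative-arm genes 8 fell (8; list fell by 1.27, adjusted p = 0.000164), with Nr1d1 at -3.41 ± 0.25 (adjusted p = 4.7e-14), Nr1d2 at -2.56 ± 0.15 and Dbp at -2.17 ± 0.33. Per2 did not change in level (0.07, adjusted p = 0.87). Among rises outside the clock was that of the imprinted noncoding RNA H19 (ENSMUSG00000000031; chromosome 7, 142575529 to 142578143) at 3.12 ± 0.31, which lay below 1 RPKM in WT (-0.49). Tissue factor F3 (1.82 ± 0.17) and Ttc9 (1.54 ± 0.14) also rose, while the steroid dehydrogenase gene Akr1c18 (-1.74 ± 0.32), the neurotrophin receptor gene Ngfr (-1.55 ± 0.14) and the mitotic phosphatase gene Cdc25b (-1.41 ± 0.10) fell.

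Genes of epidermal differentiation and lipid synthesis rose in BRE. Of 16 suprabasal genes 13 rose (14 adjusted over the list alone), with Krt1 at 0.36 ± 0.05, Krtdap at 0.39 ± 0.06 and the filaggrin-related Hrnr at 1.09 ± 0.18, and the list rose by 0.43 (adjusted p = 0.000164). Of 13 barrier lipid genes 9 rose (9), with the fatty acid elongase Elovl4 at 0.43 ± 0.06, and the list rose by 0.24 (adjusted p = 0.000164). Of 20 cholesterol synthesis genes 14 rose (15), with Fdps (ENSMUSG00000059743; chromosome 3, 89093588 to 89101959), farnesyl diphosphate synthase, at 0.53 ± 0.06, and the list rose by 0.27 (adjusted p = 0.000164). Glycolysis fell by 0.16 (adjusted p = 0.00402; 8 of 13 members lower, 8 adjusted over the list alone), with Slc2a1 at -0.33 ± 0.06 and Hk2 at -0.54 ± 0.11. The interferon list fell by 0.33 (adjusted p = 0.00115; 2 of 7, 2 adjusted over the list alone), with Bst2 at -0.78 ± 0.14, and the hair follicle list by 0.48 (adjusted p = 0.000805; 4 of 6, 4 adjusted over the list alone), with Lhx2 at -0.94 ± 0.13 and Sox9 at -0.27 ± 0.09. These falls were not particular to BRE. Against the same WT libraries, the glycolysis and hair follicle lists also fell in EpiRE and RERE, and the interferon list fell in RERE. Krt1 likewise rose in EpiRE and RERE. The barrier lipid list also rose in RERE (0.13, list permutation test, adjusted p = 0.0343), and the suprabasal list lay 0.24 higher there without passing (adjusted p = 0.0528). The antioxidant list fell by 0.07 (adjusted p = 0.0250; 6 lower and 2 higher of 14, 8 adjusted over the list alone), with Prdx6 at -0.43 ± 0.04, and the glucocorticoid response list by 0.24 (adjusted p = 0.0250; 7 of 12 lower, 8 adjusted over the list alone), with Klf9 at -0.67 ± 0.11. Both calls were lost under median-of-ratios scaling (differences of -0.03 and -0.20, adjusted p = 0.397 and 0.0979). S phase genes did not pass as a list (-0.20, adjusted p = 0.241; 5 lower and 1 higher of 19, 3 adjusted over the list alone), nor did T cell markers, of which Thy1 rose by 0.64 ± 0.14 and Nkg7, Cd3g and Cd3e fell.

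**Figure D5:**
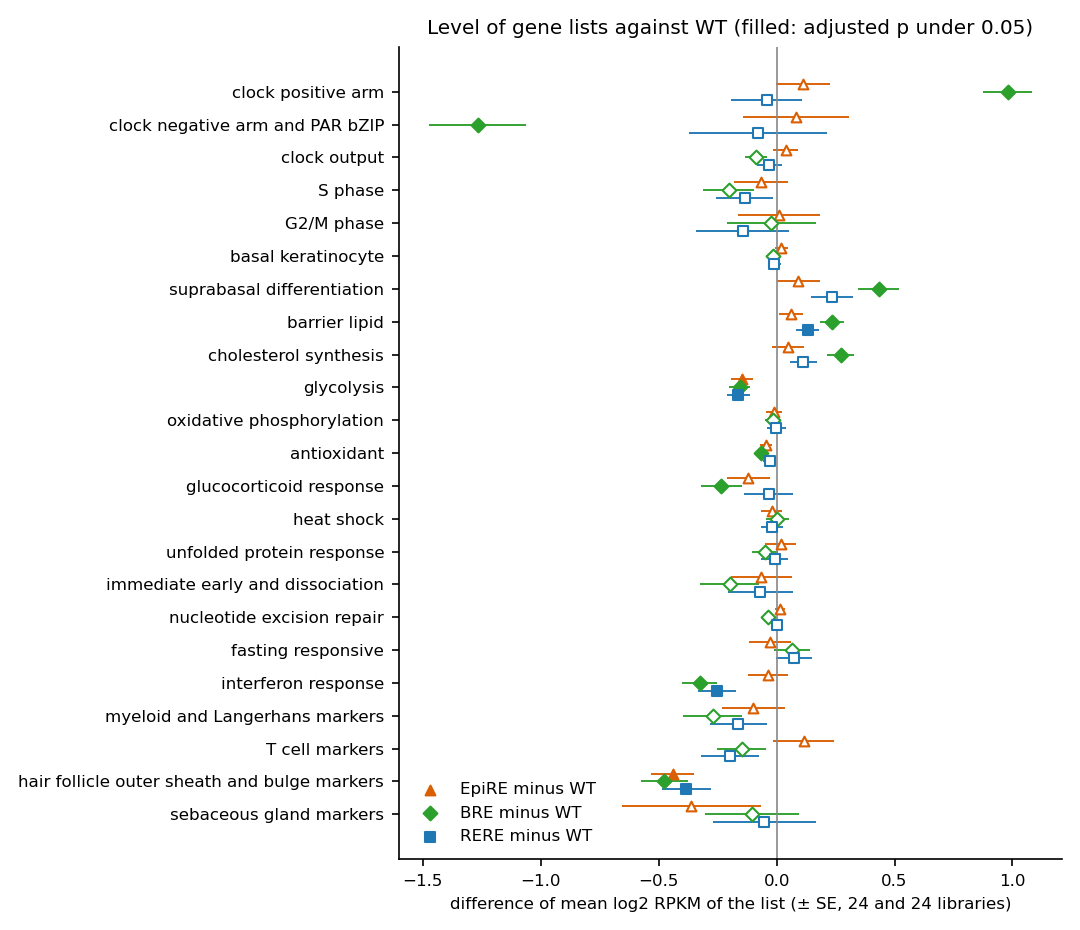
Difference of the mean log2 RPKM of each gene list from WT (points with ± SE over 24 and 24 libraries) on the x axis, for EpiRE, BRE and RERE, with the lists on the y axis and filled points for an adjusted p under 0.05. The suprabasal list (0.43) and the negative clock arm (-1.27) move furthest in BRE. Some lists move further in another genotype, such as sebaceous gland markers in EpiRE (-0.36) and T cell markers in RERE (-0.20).

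RERE and EpiRE both hold the epidermal clock and differ in the brain clock. Levels differed between them in 1 of 11042 genes, the galactosyltransferase gene B4galt4, which was 0.34 higher in RERE (adjusted p = 0.00874) and which was named after its value was seen. The count was 0 without replicate 2 and 2 by limma-voom. It was also 2 without the EpiRE library of CT4 replicate 1, CT8 replicate 1, CT16 replicate 2, CT20 replicate 1 or CT20 replicate 4, or the RERE library of CT0 replicate 3, CT4 replicate 4, CT8 replicate 4, CT12 replicate 3, CT12 replicate 4, CT16 replicate 4, CT20 replicate 2 or CT20 replicate 3. No list passed (the T cell list was nearest, at -0.31 with adjusted p = 0.0623). With pseudocount 1 or with a replicate block 1 list passed, and 0 to 2 lists did without 1 replicate number. Rhythms differed in 116 genes, among them 4 of 6 positive-arm genes (5 adjusted over the list alone), 8 of 11 negative-arm genes (10) and 8 of 19 S phase genes (19). Amplitudes in RERE and EpiRE were 0.75 and 0.09 for Pdxk (adjusted p = 5.51e-06), 0.87 and 0.14 for Cxcl14, 0.41 and 0.03 for Rdh12, 0.38 and 0.08 for Sod2 and 0.82 and 0.22 for Ccnd2. The count of 116 was 183 without the EpiRE library of CT0 replicate 3, 201 without the EpiRE libraries that stood apart, and 39, 23 and 34 without replicates 1, 2 and 4.

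RERE and BRE both hold the brain clock and differ in the epidermal clock. Levels differed in 3020 of 10991 genes, 1910 higher and 1110 lower in RERE, against 1225 and 1537 under median-of-ratios scaling. Nr1d1 lay 3.31 ± 0.23 higher in RERE and Dbp 1.99 ± 0.34, while H19 (-2.98 ± 0.29), Npas2 (-2.12 ± 0.19) and Cry1 (-1.59 ± 0.13) lay lower. The positive arm was lower by 1.02 as a list (5 of 6 lower, 5 adjusted over the list alone) and the negative arm 1.19 higher (8 of 11, 9 adjusted over the list alone; adjusted p = 0.000164 each). Cholesterol synthesis was lower by 0.16 (adjusted p = 0.0390; 10 of 20, 12 adjusted over the list alone), with Pmvk at -0.30 ± 0.05. The glycolysis (-0.007, adjusted p = 0.924), interferon (0.07, adjusted p = 0.615) and hair follicle lists (0.09, adjusted p = 0.679) were not called different. The suprabasal list (-0.20, adjusted p = 0.0704; 10 of 16 lower and 2 higher, 13 adjusted over the list alone) and the barrier lipid list (-0.10, adjusted p = 0.0846; 6 of 13 lower, 8 adjusted over the list alone) did not pass, and passed under median-of-ratios scaling (adjusted p = 0.0375 each). Rhythms differed in 461 genes, among them 4 of 6 positive-arm genes (6 adjusted over the list alone), 9 of 11 negative-arm genes (9), 16 of 18 S phase genes (17) and 5 of 20 G2/M genes (10). Ttc9 had amplitudes of 1.07 in RERE and 0.07 in BRE (adjusted p = 9.41e-10), Cxcl14 0.87 and 0.06, and the tyrosine catabolism gene Fah 0.67 and 0.05. The fitted peak of the primase gene Prim1 was at CT 13.1 in RERE and CT 0.30 in BRE (adjusted p = 1.75e-08 for the difference). The count of levels was 1873 without replicate 2, and that of rhythms was 217, 221 and 214 without replicates 2, 3 and 4.

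Sorting genes by which genotypes shared 1 rhythm placed 2522 of 11028 genes with a weight of at least 0.5. The largest class, 733 genes (29.1%), was rhythmic alike in WT and RERE and not in the others, and held Rdh12 and, of the clock, Clock, Cry1, Per3, Cry2 and Hlf. A shared rhythm in WT, RERE and EpiRE fitted 542 genes (21.5%), such as the transporter gene Slc6a20a (0.43, 0.37 and 0.38) and Ywhaz. A shared rhythm in WT, RERE and BRE fitted 412 genes (16.3%), such as Fkbp5 (0.81, 0.88 and 1.01), Klf13, Prss23 and Per1. All 4 genotypes shared the rhythm in 367 genes (14.6%), Smad3 among them. Smaller classes were a rhythm in WT (83 genes, Dgka and Xpc), in WT and BRE (70, Tmem33 and Hdac3), 1 rhythm in WT and RERE beside another in EpiRE and BRE (55, Fbxo3 and Stk35), 1 in WT and RERE beside another in BRE (50), in WT and EpiRE (36, Tnip2 and Nr4a2) and in WT, EpiRE and BRE (21). The class with a rhythm of its own in BRE held Prim1, Gins2, E2f1, Mcm6 and the DNA methyltransferase gene Dnmt1. At a weight of 0.8 the 4 largest classes held 240, 126, 86 and 56 genes. Without 1 replicate number at a time they held 407 to 583, 194 to 456, 194 to 283 and 165 to 436. A place in a class with EpiRE rests on this sorting, as limma called 0 genes rhythmic in EpiRE by itself. In BRE by itself limma called 125, fewer than the 412 genes of the class shared by WT, RERE and BRE. Most places in that class therefore rest on the sorting too.

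The deposited statistics of the authors' programs, read at a q-value under 0.05 in both, gave 915 rhythmic genes in WT, 212 in RERE, 0 in EpiRE and 0 in BRE, of which WT and RERE shared 105, where 8.62 would be shared by independent lists. Of the WT consensus genes tested here 855 of 856 were called by the cosine fit as well, and 192 of 192 in RERE. The consensus held 14 clock list genes in WT and 7 in RERE. For EpiRE and BRE the deposited p-values of both programs lay under 0.01 for 45 and 283 genes, and limma called 0 and 125 with 1397 and 2071 at an unadjusted p under 0.05 (0 and 169 by limma-voom).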

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

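Of the tests in this part, the search for libraries standing apart and the interaction tests were set before the values were seen, and leaving out EpiRE and BRE libraries was chosen after. Within each group of 4 libraries, a library was marked where its gap to the nearest other took up more of the group's range than chance gives 1 time in 20 (Dixon's Q, two-sided). For total reads, Arntl and clock magnitude 72 groups were tested and 10 passed, where 3.6 were expected by chance.

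Total reads stood apart in 4 groups. BRE CT0 replicate 4 had 12.6 M where the others had 18.5 to 18.6 M (Q = 0.972). EpiRE CT16 replicate 1 had 16.4 M against 11.4 to 11.7 M (Q = 0.937). WT CT20 replicate 2 had 17.8 M against 12.8 to 13.2 M (Q = 0.927), and WT CT8 replicate 1 had 12.1 M against 16.2 to 16.8 M (Q = 0.876). Arntl stood at 4.60 in EpiRE CT20 replicate 1 against 4.04 to 4.11 (Q = 0.879).

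The magnitude of the clock state stood apart in 5 groups. It was 0.676 in BRE CT20 replicate 1 against 0.0889 to 0.127 (Q = 0.934), 1.12 in EpiRE CT0 replicate 3 against 0.266 to 0.385 (Q = 0.860) and 0.972 in EpiRE CT20 replicate 1 against 0.0987 to 0.190 (Q = 0.896). In RERE it was 1.09 in CT20 replicate 4 against 0.858 to 0.890 (Q = 0.867) and 1.41 in CT4 replicate 3 against 0.793 to 0.880 (Q = 0.859). EpiRE CT20 replicate 1 stood apart in both Arntl and clock magnitude. The causes were not tested, and all libraries were kept.

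The effect of time differed between genotypes, tested by interaction, in 174 genes for EpiRE against WT, 627 for BRE against WT, 116 for RERE against EpiRE and 461 for RERE against BRE.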

How the results depend on the processing

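Of the settings in this part, limma-voom and leaving out the EpiRE and BRE libraries standing apart were chosen after the results were seen. Over 62 results, 282 of 350 values under other settings kept the result, and 68 changed it by over 1.5-fold, across its threshold, beyond its error or in sign. Leaving out libraries gave 808 values, of which 692 kept the result and 116 changed it. Lists that rest on a single count of genes should be read with these ranges, and the causes of the changes were not tested.

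At an adjusted p under 0.01 rhythmic genes numbered 1732 in WT, 947 in RERE and 2 in BRE. Differential rhythm then held 54 genes for EpiRE against WT, 324 for BRE against WT, 45 for RERE against EpiRE and 245 for RERE against BRE, and levels 97, 2697 and 76 for EpiRE, BRE and RERE against WT and 1797 for RERE against BRE. With CT as a factor 2249 genes were called in WT, 199 in EpiRE and 31 in BRE, and differential rhythm held 109 genes for EpiRE against WT, 285 for BRE against WT and 286 for RERE against BRE. The spread shared over 96 libraries called 94 genes in EpiRE. Rhythmic genes in BRE were 54 without a filter and 76 without a trend. With a mean of 5 or more, differential rhythm held 68 genes for RERE against EpiRE and 260 for RERE against BRE, levels held 128 for EpiRE against WT and 0 for RERE against EpiRE, and the class with 1 rhythm in WT and RERE and another in BRE held 26. Without a CT term levels held 149 genes for EpiRE against WT, 81 for RERE against WT and 0 for RERE against EpiRE. The 1 gene of RERE against EpiRE became 2 with pseudocount 1, 2 with median-of-ratios scaling, 2 when quantile normalised, 2 by limma-voom and 4 without a filter. Without the EpiRE and BRE libraries standing apart, differential rhythm held 294 genes for EpiRE against WT and 201 for RERE against EpiRE, and the part of the EpiRE clock state locked to CT was 0.169.

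Arntl in BRE minus WT was -0.00975 with pseudocount 1 (permutation p = 0.935), and BRE minus RERE was 0.0203 under median-of-ratios scaling (permutation p = 0.871), both of the other sign and near 0. Under median-of-ratios scaling 0 lists were rhythmic in BRE and 5 lists differed in level for RERE against BRE, and the arm correlation was 0.0952 in WT and 0.607 in BRE (permutation p = 0.00772). With pseudocount 1, 1 list differed in level for RERE against EpiRE. The template clock genes alone gave a phase difference of 0.498 h for RERE against WT and an amplitude ratio of 0.235 for EpiRE against WT. At a BIC weight of 0.8 or more the classes, in the order given in the results, held 240, 126, 86, 56, 8, 9, 12, 11, 2 and 0 genes. The authors' consensus with both p under 0.01 held 1781 genes in WT, 1041 in RERE, 45 in EpiRE and 283 in BRE, with both q under 0.1 it held 1712 in WT and 532 in RERE, and JTK_CYCLE alone held 2187 in WT, 1231 in RERE and 3 in BRE.

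With a replicate block rhythmic genes in BRE were 41, Arntl in EpiRE minus WT was 0.28 (permutation p = 0.0776), and the lists that differed in level were 1 for RERE against EpiRE and 7 for RERE against BRE. Residuals of libraries with the same number correlated by 0.004 on average (256 of 1104 pairs over 0.1), those with different numbers by -0.001 (730 of 3312). At the same CT in different genotypes the averages were 0.0197 (44 of 144) and -0.00639 (93 of 432), and 32 of 96 libraries correlated best with their own number. Pairs were to be read from the numbers only where every correlation was over 0.1, which did not hold in this replicate check.

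Leaving out each library and each replicate number in turn, rhythmic genes ranged from 2019 to 4021 in WT, 875 to 2137 in RERE, 0 to 2 in EpiRE and 0 to 348 in BRE. Differential rhythm ranged from 37 to 293 for EpiRE against WT, 305 to 741 for BRE against WT, 0 to 1 for RERE against WT, 23 to 183 for RERE against EpiRE and 214 to 494 for RERE against BRE. Levels ranged from 55 to 284 for EpiRE against WT, 48 to 333 for RERE against WT, 0 to 2 for RERE against EpiRE and 1873 to 3318 for RERE against BRE. Arntl ranged from -0.00688 to 0.0182 in BRE minus WT, -0.0379 to 0.0214 in BRE minus RERE, 0.27 to 0.289 in EpiRE minus WT and -0.0209 to 0.0465 in RERE minus WT. Rhythmic lists ranged from 3 to 5 in WT, 3 to 5 in RERE and 0 to 1 in BRE, and lists that differed in level from 1 to 2 for EpiRE against WT, 1 to 7 for RERE against WT, 0 to 2 for RERE against EpiRE and 2 to 5 for RERE against BRE. The difference of clock magnitude between RERE and WT ranged from -0.0549 to 0.00457, the arm correlation in WT from -0.532 to 0.164 and the phase difference of RERE from -0.712 to 0.0796 h.

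Without 1 replicate number, the class shared by WT and RERE ranged from 407 to 583 genes, that with EpiRE from 194 to 456, that with BRE from 194 to 283 and that of all genotypes from 165 to 436. WT alone ranged from 23 to 115, WT with BRE from 17 to 68, WT and RERE beside EpiRE and BRE from 11 to 108, WT and RERE beside BRE from 26 to 37, WT with EpiRE from 10 to 29 and WT with EpiRE and BRE from 10 to 59.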

Other observations

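In EpiRE some genes differed between times without following a 24 h cosine, and those named here were chosen after their values were seen. All 4 tested sebaceous gland markers were called with CT as a factor (4 adjusted over the list alone), and 4 of 12 immediate early and dissociation genes (10). Mgst1, a microsomal glutathione transferase, stood at 5.30 (SD 0.65, n = 4) at CT8 and 3.07 (SD 0.23, n = 4) at CT12. The fatty acid desaturase gene Scd1 stood at 7.59 (SD 0.11, n = 4) at CT8, and Cd24a at 5.57 (SD 0.07, n = 4) at CT0 and 4.77 (SD 0.19, n = 4) at CT16. With 4 animals per time, a share of sebaceous gland in the separated tissue that differs between times may give the values of its markers. Most of the 199 genes had another time course than Mgst1 and Scd1. Of them 77 were highest at CT16, 46 at CT0 and 47 at CT8, while 77 were lowest at CT0 and 77 at CT16. EpiRE totals were 17.3 to 18.5 M reads at CT0 and 11.4 to 16.4 M at CT16, and an effect of depth was not tested. The time differences rested on the factor fit (199 genes) where the cosine fit called 0.

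In this part the tests of no running clock, of uneven composition and of a wider spread were chosen after the result was seen. Chance was tested with 100 splits of the libraries, the real one included, made by shuffling CT for rhythms and genotype within CT for contrasts. For rhythms the real count was reached by 1 of 100 splits in WT (3675, highest other 3), 1 in RERE (2136, highest other 3) and 1 in BRE (125, highest other 4), and by 100 in EpiRE (0, highest other 1). For differential rhythm it was reached by 1 of 100 for EpiRE against WT (174, highest other 1), 1 for BRE against WT (627, highest other 37), 1 for RERE against EpiRE (116, highest other 20) and 1 for RERE against BRE (461, highest other 45), and by 100 for RERE against WT (0, highest other 7). For levels it was reached by 1 of 100 for EpiRE against WT (247, highest other 25), 1 for BRE against WT (4066, highest other 2) and 1 for RERE against BRE (3020, highest other 112). For RERE against WT 2 of 100 reached 236 and the highest other was 333, and for RERE against EpiRE 3 of 100 reached 1 and the highest other was 8. In these last contrasts another split gave more calls than the real one, and the cause was not tested.

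The EpiRE libraries held a clock state and no rhythm called by CT. The magnitude of the state was larger in EpiRE than in BRE (permutation p = 0.00045). A wider spread of the clock genes from any source would also raise it, so the magnitude does not decide whether a clock ran. The part locked to CT was 0.243 ± 0.063, against 0.048 ± 0.023 in BRE. It was smaller without the EpiRE libraries that stood apart. So the absence of a running clock, as in BRE, was not settled. Clocks of single animals that ran at different phases might give a clock state without a called rhythm. EpiRE libraries named with a wrong CT might do so too, which was not tested. After subtraction of the BRE magnitude in squares, the ratio of locked to mean magnitude in EpiRE was 0.730 where under 0.7 was needed, so it could not be told. Uneven composition of the samples could not be told either: the spread within times in EpiRE relative to BRE was 1.5 times as large for clock genes as for all genes, but these genes also define the state, and the ratio of SD in EpiRE to BRE was 1.69 for clock genes, 1.31 for sebaceous gland markers and 1.12 for all genes.

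The BRE count of 125 rhythmic genes could rest on single libraries, as it was 32 without CT16 replicate 4, though it was 348 without CT16 replicate 3. It could also come from signals of the body that reach the epidermis without its clock, as peaks of the BRE genes lay in the median 1.96 h from their peaks in WT, where random gene sets gave 3.36 h. The 2 readings do not exclude each other. A test would be the same times with more animals and measured corticosterone, feeding and temperature.

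RERE had fewer genes called rhythmic than WT, 2136 against 3675. A difference of counts is not a test of rhythm, and the interaction test called 0 of 11051 genes. With libraries or replicate numbers left out, the counts ranged from 2019 to 4021 in WT and 875 to 2137 in RERE. A lower mean depth was argued against, because WT libraries thinned to at most the mean depth of RERE still gave 3635. Depth in RERE also differed between times, with 16.9 to 19.9 M reads at CT0 and 12.1 to 13.0 M at CT20. The thinning did not copy this difference, so its effect on the count was not tested. A smaller amplitude may add to the lower count, but the ratio of 0.886 ± 0.148 could not be told from 1. A wider spread between libraries could not be told either, with a ratio of the residual SD of 0.986 ± 0.0853. If the difference of counts holds, clocks in further tissues might sharpen the epidermal rhythm, which was not tested here. A test would be RERE mice with Arntl also restored in liver or in the adrenal gland.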
